A study of Mus musculus with 6 samples.

How the data were processed

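ATAC-seq peak lists of 6 libraries were analysed, 3 from cells in 5.5 mM and 3 from cells in 25 mM glucose for 48 h. Per the labels, each library was made from 54000 cells at passage 6 and sequenced as 50 bp paired-end reads. Groups and replicate numbers came from the labels. Each library had its own deposited list, so peaks were called per sample as far as the files show. Per the submitters' processing notes, which give neither roles nor settings, reads were processed on mm10 with FastQC, cutadapt 1.0, Bowtie 1.0.0, SAMtools 0.1.19, Picard 1.90, MACS2 2.1.0 and DiffBind 1.12.3. Whether reads were shifted for the transposase offset, and how duplicates and mitochondrial reads were treated, is not given in the sources used here.

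The deposited lists give, for each peak, its position and summit, a score, a fold enrichment ratio, and the −log10 of a p-value and of a q-value, all the authors' own values as their peak caller wrote them. The lowest −log10 q-value in the deposited lists was 1.30, which corresponds to a q of 0.05. The lists hold no read counts, so depth is unknown and only the presence or absence of a peak was compared between libraries. A deeper library passes the same threshold at weaker sites, so list length can change every count of regions. The authors' −log10 p ranked peaks within 1 list only, as a percentile, and percentiles of lists of different length show no change between libraries.

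Before the data were examined, the groups, tests, alternatives, 23 gene lists and the rule for named genes were fixed. So was a minimum of 1000 peaks for a library to enter comparisons of regions, set from the listed file sizes, in which 1 normal-glucose file was far smaller. Peaks on chromosomes 1 to 19, X and Y were merged into regions where they overlapped by at least 1 bp. A region was specific to a condition when every entering library of that condition and none of the other held a peak. Means were compared by exact permutation tests, two-sided. The difference of mean Jaccard indices within and between conditions was tested one-sided over the 10 splits of the 5 libraries. The smallest possible p was 0.1 for 3 against 3 libraries and for the 10 splits, and 0.2 for 2 against 3. Gene lists were compared by two-sided Fisher's exact tests, adjusted by Benjamini-Hochberg over the 23 lists, with regions or genes as units, which are not biological replicates. Intervals on shares are 95% Wilson intervals.

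Genes were the 21887 protein-coding genes of the RefSeq annotation of GRCm38.p6, which has the coordinates of mm10, and 719 different genes made up the lists. The annotation used gave the start and end of each gene but neither strand, exons nor alternative starts. The promoter windows fixed beforehand therefore became windows of 1 kb either side of both ends of a gene, called gene ends, and a gene with such a peak was called open. A region was assigned to the genes it overlapped, otherwise to the nearest gene within 100 kb. After moving every peak by 50000 bp, 6.31% to 6.98% lay at a gene end, against 32.2% to 45.4% in place. No genome sequence was used, so the planned search for 18 sequence motifs was not run.

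Named genes were Nos3, Jarid2, Notch1 and Txnip, with 10 kb either side. To these were added, per direction, the 12 genes at whose end a specific region lay with the highest rank in the library where it was weakest, and up to 15 list members with a specific gene end. For cushion, mesenchymal and glycolysis genes the 3 highest ranked members open in all 5 libraries were also named. Gene models and clones without a proper symbol were passed over, and some genes that the rule selects are not reported here.

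Other settings fixed beforehand were a −log10 q of at least 5, lists of equal length (the top 22149 by −log10 p), all 6 libraries, each library left out, other overlaps and windows, and same-numbered libraries as pairs. Added after seeing the data were merging within 200 bp, the test of each list's openness against all other genes, and the same test over whole genes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 was used, and overlaps were checked with bedtools 2.31.1. The region calls were run on simulated data with 49048 regions, list lengths as measured and 200 regions planted for each condition. All planted regions were recovered, which was fixed by construction. Each was listed in every library of its condition and in none of the other, so recovery does not measure the power to find real regions. Beyond the planted ones the simulation called 93 high-glucose and 2521 normal-glucose regions with full lists, and 419 and 723 with equal lengths, although it held no other difference between the conditions. Its regions and their strengths came from these same lists, and its noise level was set without fitting it to the agreement between replicates. The size of these counts is therefore not a calibrated reference for the observed ones.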

Results

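Open chromatin was profiled by ATAC-seq, in which a transposase cuts and tags accessible DNA, in an immortalised mouse line of atrioventricular cushion mesenchymal cells. These cells derive from the embryonic tissue that forms the heart valves and septa. They were kept for 48 h in medium with 5.5 mM glucose (normal glucose, 3 libraries) or 25 mM glucose (high glucose, 3 libraries). The series addresses how high maternal glucose relates to congenital heart disease, and the design asks whether glucose alters the open chromatin of these cells. One peak list per library was analysed. The normal-glucose lists held 24263, 66 and 40350 peaks for replicates 1, 2 and 3, and the high-glucose lists held 22156, 25020 and 22598. Normal-glucose replicate 2, with 66 peaks, fell under the 1000-peak minimum and entered no comparison of regions, which left 2 normal-glucose and 3 high-glucose libraries. Nothing in the labels says that replicates came from separate cultures, so permutation p-values measure only the spread between these libraries, which may be technical. Fisher's exact tests take genes or regions as units and measure no spread between libraries. Sequencing depth in reads is unknown, and intervals on shares of peaks cover counting error only.

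In the open chromatin common to both conditions, markers of endothelium, blood and heart muscle were less often open than other genes, while genes of cushion and valve development were more often open with lists as deposited. Of 66 genes of endocardial cushion and valve development, 33 had a peak within 1 kb of a gene end in all 5 libraries, against 35.7% of other protein-coding genes (adjusted exact p = 0.0306, Fisher's exact test). They included Snai1 and Snai2, repressors that act in epithelial-to-mesenchymal transition, the transcription factors Sox9, Tbx3, Gata6, Hand2 and Foxc1, and the receptors Tgfbr1, Tgfbr2 and Tgfbr3. None of 24 endothelial markers was open in all 5 libraries (adjusted exact p = 2.40e-04), and Pecam1, Cdh5 and Tek had no gene-end peak in any of them, although Kdr and Flt4 had one in 4 of the 5. Of 24 blood cell markers 1 was open in all 5, Spi1 (adjusted exact p = 0.00174), and of 24 cardiomyocyte markers 2 were, Nppb and Atp2a2 (adjusted exact p = 0.00930). The cushion call was not reached with lists of equal length (adjusted exact p = 0.0748), while the endothelial, blood and cardiomyocyte calls were.

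Cushion genes open in all 5 libraries were ranked by the gene-end peak in the library where each was weakest. The highest were Tgfbr1, Tbx20 and Fbln2, which encodes an extracellular matrix fibulin. Their peaks stood at or above the 93.4, 92.1 and 91.6 percentile of each library's own list, ranked by the authors' −log10 p. Cushion genes without a gene-end peak in any of the 5 libraries included Bmp2, Bmp4, Tbx5, Nkx2-5 and Hapln1. Of 44 mesenchymal and fibroblast markers 21 were open in all 5 libraries, which did not pass the test against other genes (adjusted exact p = 0.146, Fisher's exact test). They included Vim, Acta2, Tagln, Fn1, Cdh2 and Cdh11, although Acta2 and Cdh11 fell to the 12.9 and 16.1 percentile in their weakest library. The strongest by the same ranking were Tagln, Cd44 and Vim, at or above the 79.4, 72.2 and 68.9 percentile. The 11 members without a gene-end peak in any library were Pdgfra, Pdgfrb, Thy1, Col1a2, Col6a3, Lum, Eln, Loxl2, Tcf21, Ddr2 and Fap. Of 19 epicardial and epithelial markers 3 were open in all 5, Wt1, Upk1b and Upk3b (adjusted exact p = 0.125). This pooled list was mixed. Upk3b and Wt1 stood at or above the 87.3 and 82.2 percentile, and Tbx18, Msln, Muc16, Lrrn4, Bnc1 and Bnc2 were open in some libraries. The 10 members with no gene-end peak in any library were Krt8, Krt18, Krt19, Epcam, Cdh1, Cldn4, Cldn7, Esrp1, Aldh1a1 and Aldh1a2.

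Of 3 lists of glucose handling, 2 were open in all 5 libraries more often than other genes. Of 35 genes of glycolysis and glucose uptake 22 had a gene-end peak in all 5 libraries (adjusted exact p = 0.00314, Fisher's exact test), among them Slc2a1, the main basal glucose transporter, and the glycolytic enzymes Hk2, Gapdh and Pkm. Ranked by the library where each was weakest, the strongest were Pgam1, Eno1 and Pfkl, at or above the 99.3, 96.1 and 91.2 percentile of every list. Of 27 genes of glucose-responsive transcription 17 were open in all 5 (adjusted exact p = 0.00930). They included Txnip, a classical glucose-induced gene, Mlx and Mlxip, while Mlxipl, which encodes the ChREBP factor, had no gene-end peak in any library. In the polyol and hexosamine pathways 9 of 15 members were open in all 5, including Akr1b3, Gfpt1 and Oga, which did not pass the test against other genes (adjusted exact p = 0.0866).

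Stress and growth programmes were open more often than other genes by the same test. Among these lists were the unfolded protein response, with 22 of 26 members (adjusted exact p = 9.31e-06), including Hspa5, Xbp1 and Atf4, and Hippo and YAP targets, with 20 of 24 (adjusted exact p = 2.63e-05), including Yap1, Tead1 and Ccn2. Cell cycle genes had 26 of 37 members open in all 5 (adjusted exact p = 1.65e-04), AP-1 and immediate early genes with 19 of 27 (adjusted exact p = 0.00168), and ribosomal protein genes with 29 of 48 (adjusted exact p = 0.00232). Apoptosis and p53 targets had 16 of 26 (adjusted exact p = 0.0146), and the oxidative stress response had 22 of 39 (adjusted exact p = 0.0181), with Nfe2l2, Hmox1 and Sod2. Histone methylation and demethylation had 24 of 38 (adjusted exact p = 0.00277), including Jarid2, Ezh2, Eed and Suz12, and Notch signalling had 21 of 37 (adjusted exact p = 0.0170), including Notch1, Notch2, Jag1, Hey1 and Hey2. Notch1 counted as open through different gene-end regions in different libraries. Its sole gene-end region in high-glucose replicate 3 stood at the 2.68 percentile of that list. The test against other genes was not passed by DNA methylation and histone deacetylation, with 13 of 26 members (adjusted exact p = 0.184), nitric oxide signalling, with 11 of 27 (adjusted exact p = 0.754), and congenital heart disease genes, with 19 of 46 (adjusted exact p = 0.510). Nor was it passed by Wnt and Hedgehog signalling, with 12 of 32 (adjusted exact p = 0.893), or inflammation and NF-kB, with 11 of 32 (adjusted exact p = 1). In all, 12 of the 23 lists were open more often than other genes, ribosomal protein genes included. Of all protein-coding genes 48.0% had no gene-end peak in any of the 5 libraries, which makes the test easy to pass. No other cell type was compared, so such openness is not shown to be particular to these cells.

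**Figure D1:**
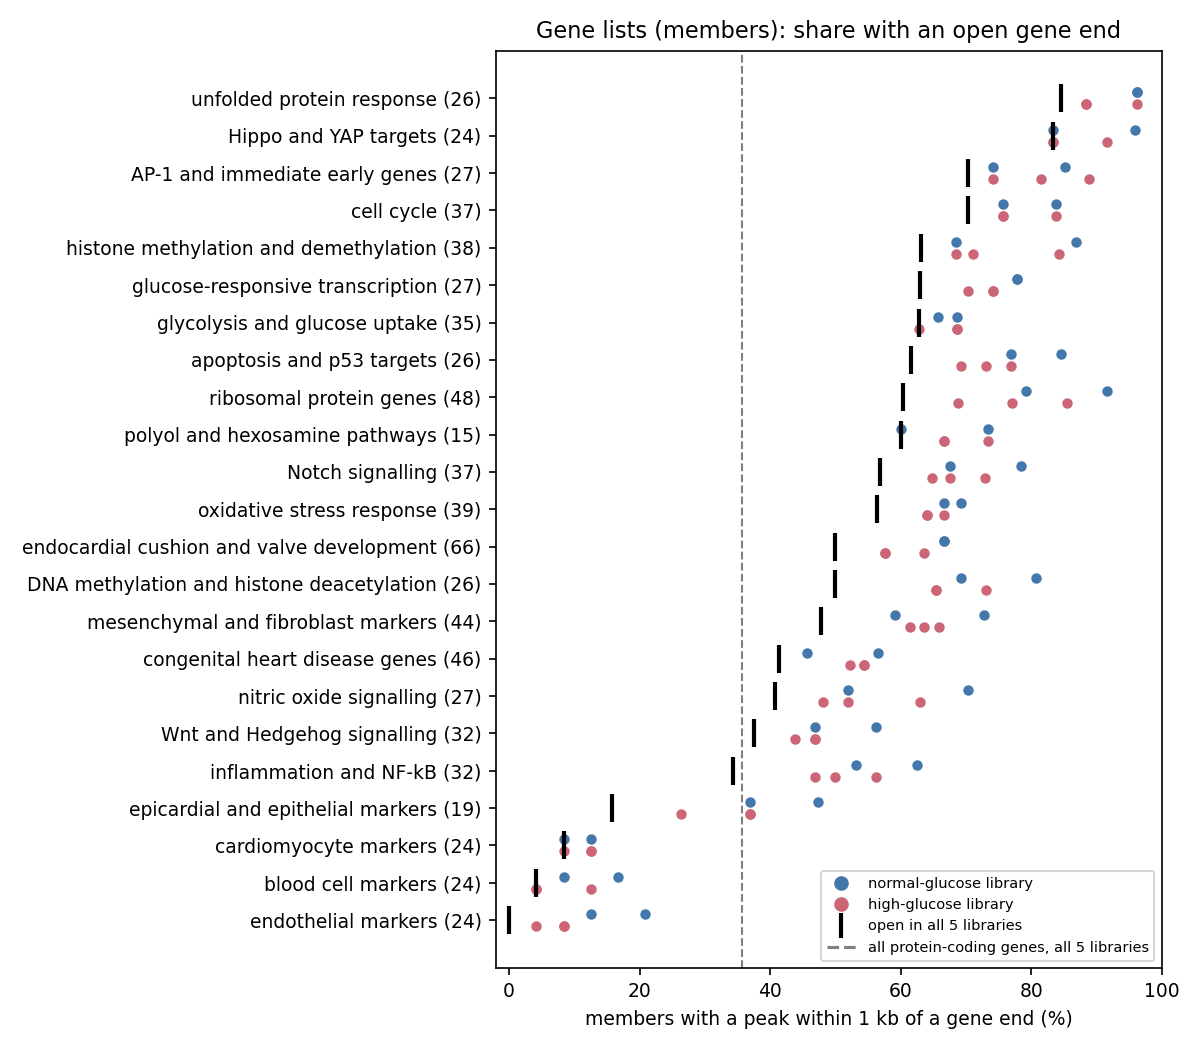
Share of each gene list's members (%) with a peak within 1 kb of a gene end, in each normal-glucose (blue) and high-glucose (red) library. Black bars mark members open in all 5 libraries, the number of members is in parentheses, and the dashed line marks the 35.7% of all protein-coding genes open in all 5. Endothelial, blood and cardiomyocyte markers lie far to the left of that line.

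A gene without a gene-end peak was not necessarily closed, because starts inside a gene fall outside these windows. Nor was an open gene necessarily open at its start, because either end counted and a window can reach a neighbouring gene. Of the 10505 protein-coding genes with no gene-end peak in any of the 5 libraries, 1151 (11.0%) held a peak inside the gene in all 5. These included Cdkn1a, Mcl1, Dnmt1, Hk1 and Aldoa, genes chosen here after their values were seen. With peaks anywhere inside a gene or within 1 kb of it, 4 of 24 endothelial, 4 of 24 cardiomyocyte and 1 of 24 blood cell markers were open in all 5 libraries, the endothelial gene Vwf among them, against 44.6% of other genes (adjusted exact p = 0.0106, 0.0106 and 8.63e-05, Fisher's exact test). By that measure 27 of 44 mesenchymal markers were (adjusted exact p = 0.0440), 19 of 26 genes of DNA methylation and histone deacetylation (adjusted exact p = 0.00998) and 11 of 15 of the polyol and hexosamine pathways (adjusted exact p = 0.0448), 3 calls that gene ends did not give. The other calls and directions were as with gene ends. A longer gene has more room for such a peak, and gene length was not taken into account in these tests.

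The number of peaks and their placement did not differ detectably between the conditions. High-glucose libraries held 23258 ± 1542 peaks (SD, n = 3) and normal-glucose libraries 21560 ± 20278 (SD, n = 3), a difference of 1698 (p = 0.9, two-sided exact permutation test, smallest possible p 0.1). Without normal-glucose replicate 2 the sign turned, to a difference of -9048.5 (p = 0.4, exact permutation test). Peaks within 1 kb of a gene end made up 43.4% ± 1.72 of nuclear peaks in high glucose (SD, n = 3) and 36.8% ± 6.52 in normal glucose (SD, n = 2). That difference of 6.63 percentage points had p = 0.2 (two-sided exact permutation test), the smallest p that 2 against 3 libraries allow. The 2 normal-glucose libraries lay apart, at 41.4% (95% Wilson interval 40.8 to 42.0) for replicate 1 and 32.2% (31.7 to 32.6) for replicate 3. The high-glucose libraries lay at 42.3%, 42.5% and 45.4% for replicates 1, 2 and 3. Without normal-glucose replicate 3 the difference was 2.02 points and without normal-glucose replicate 1 it was 11.2, and lists of equal length gave 1.99 (p = 0.4, exact permutation test).

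**Figure D2:**
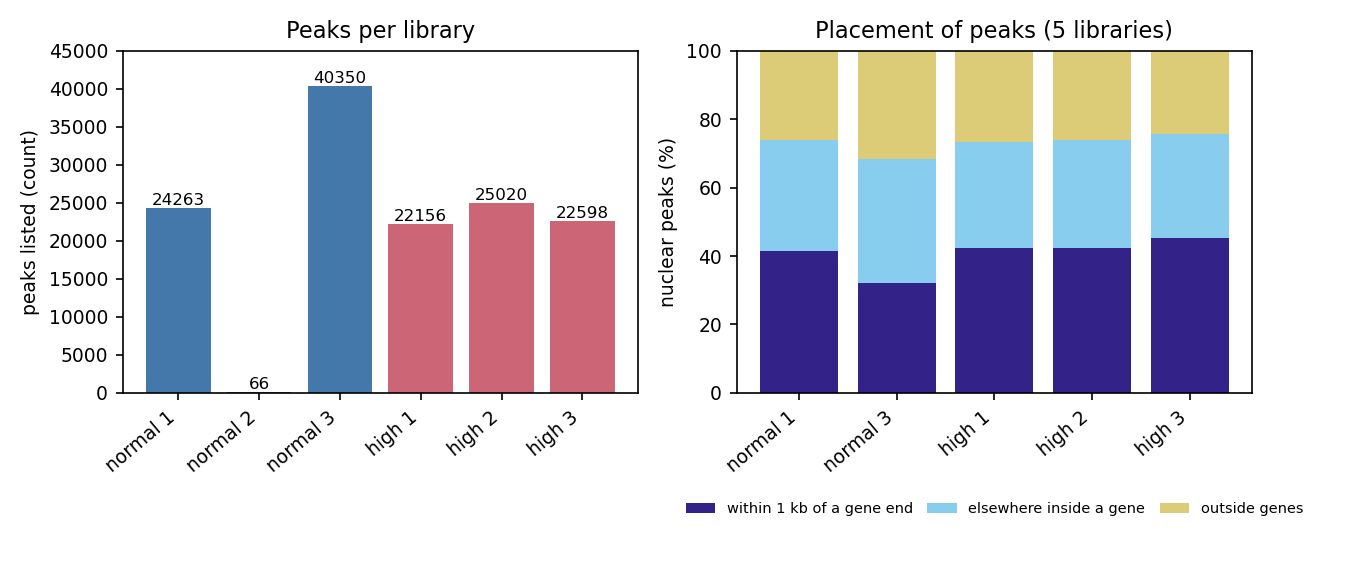
Left, peaks listed in each of the 6 libraries (count), with normal glucose in blue and high glucose in red. Right, placement of nuclear peaks (%) in the 5 libraries with at least 1000 peaks, where normal-glucose replicate 3, with 40350 peaks, has the smallest share at gene ends (32.2%).

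The peak sets of the 2 conditions overlapped about as much as replicates did. Peaks of the 5 libraries merged into 49048 regions, of which 12321 (25.1%) were present in all 5 and 19459 (39.7%) in a single library. Of the latter, 11560 were in normal-glucose replicate 3. The Jaccard index of shared regions averaged 0.524 within and 0.499 between conditions, a difference of 0.0251, the highest of the 10 splits of the 5 libraries (p = 0.1, one-sided exact permutation test, the smallest possible). With every list at the length of the shortest, 22149 peaks, the sign turned to -0.00366, and 8 of the 10 splits were as high (p = 0.8, exact permutation test). At that length normal-glucose replicate 3 had an index of 0.563 with its own replicate, and of 0.558, 0.574 and 0.575 with high-glucose replicates 1, 2 and 3.

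**Figure D3:**
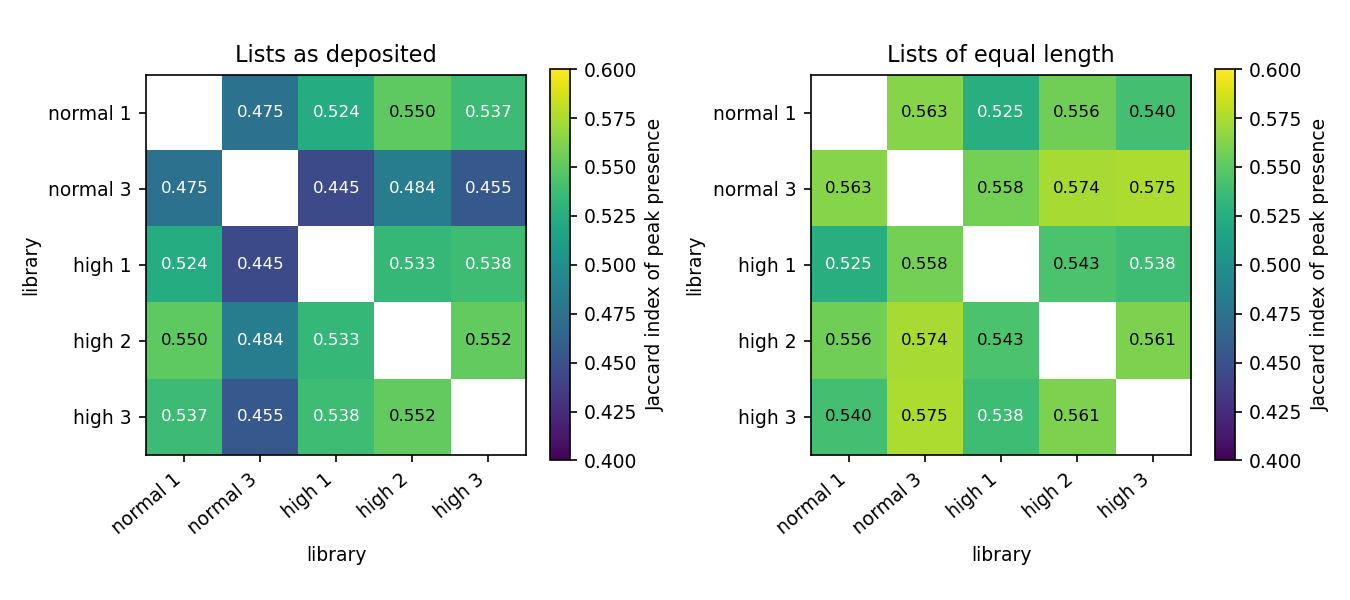
Jaccard index of peak presence for each pair of the 5 libraries, with lists as deposited (left) and at equal length (right). As deposited, normal-glucose replicate 3 has the lowest indices (0.445 to 0.484), while at equal length all pairs lie between 0.525 and 0.575.

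Regions present in all 3 high-glucose and neither normal-glucose library numbered 82, and 42 protein-coding genes held such a region within 1 kb of a gene end. Among them was Nrtn, the neurotrophic ligand neurturin, with a region at chromosome 17, 56757542 to 56757668 (mm10), over the end of the gene at 56757548. Its peak stood at the 36.6, 56.6 and 41.7 percentile in high-glucose replicates 1, 2 and 3, and no normal-glucose library had a peak at either end of Nrtn. The same held for Gpr3, a G protein-coupled receptor, Psmb5, a catalytic proteasome subunit, and Hps4 and Srrd, which share 1 region between them. At Bcas3, Zfp36l1, Tbl1xr1, Sod1, Hsp90ab1 and Rabep2, the specific region lay beside other gene-end peaks that normal-glucose libraries did hold. Sod1 encodes a superoxide dismutase of the oxidative stress list and Hsp90ab1 a chaperone of the nitric oxide list. Gene by gene, 14 genes had a gene-end peak in every high-glucose and no normal-glucose library. The only list member among them was Myd88, an adaptor of Toll-like receptors, and there the region itself was present in all 5 libraries and only the edges of its peaks crossed the 1 kb limit.

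Specific regions of either condition ranked low in their lists. The median percentile of high-glucose regions was 24.0, 31.1 and 23.1 in high-glucose replicates 1, 2 and 3, and that of normal-glucose regions was 25.6 and 35.6 in normal-glucose replicates 1 and 3. In the same order of libraries, medians were 70.9, 74.2, 71.1, 72.4 and 83.8 for regions present in all 5 libraries. At a gene end lay 41.5% of the high-glucose regions (34 of 82, 95% Wilson interval 31.4 to 52.3). For regions present in all 5 libraries that share was 56.1%. Of the 10 splits of the 5 libraries 8, the real one included, gave at least 82 regions, with up to 1186. Other splits with normal-glucose replicate 3 in the pair required to lack the peak gave 51, 80 and 93. Splits with that library among the 3 required to hold it gave 561 to 1186, so the rank largely follows the place of that list. The high-glucose count was 154 without normal-glucose replicate 1, 1184 without normal-glucose replicate 3, the longest list, and 318, 237 and 282 without high-glucose replicates 1, 2 and 3. Fewer libraries make the requirement easier to meet. That alone does not account for the gap between 154 and 1184, which both left out a single normal-glucose library. The gene count of 14 likewise became 28 and 362 without normal-glucose replicates 1 and 3, and 40, 26 and 28 without high-glucose replicates 1, 2 and 3.

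Regions present in both normal-glucose and no high-glucose library numbered 1831, and 359 genes held one within 1 kb of a gene end. The highest ranked were at Zfp442, a zinc finger gene, at chromosome 2, 150451464 to 150451587, and at Cox19, a cytochrome c oxidase assembly factor, at chromosome 5, 139344164 to 139344281. At Zfp442 the peak stood at the 75.6 and 76.9 percentile in normal-glucose replicates 1 and 3, and at Cox19 at the 72.6 and 73.9. Then came Ralgps2, Rasal2, Shb, Lrrn4cl, Kank2, H2-M5, Vwa5a, Mfsd3 and a region shared by Mastl and Yme1l1, with a lowest percentile between 55.3 and 68.9. Of these named genes only Zfp442 and H2-M5 lacked any other gene-end peak in high glucose. Gene by gene, 153 genes had a gene-end peak in both normal-glucose and no high-glucose library, and 7 belonged to a list. They were Srebf1, a regulator of lipid synthesis, Col3a1, a fibrillar collagen, Ccl7, a chemokine, Wnt5b, a Wnt ligand, Gucy1a2, a subunit of the nitric oxide receptor guanylate cyclase, Rps24, a ribosomal protein, and Cd4, a T cell co-receptor. With lists of equal length Col3a1, Ccl7, Wnt5b, Gucy1a2, Rps24 and Cd4 were no longer specific, while Zfp442, H2-M5 and Srebf1 were, as were Nrtn, Hps4, Srrd, Gpr3, Psmb5 and Myd88 for high glucose. At a −log10 q of at least 5 the same 6 normal-glucose genes and Nrtn, Gpr3 and Psmb5 were no longer specific. Windows of 2.5 kb ended specificity for Gpr3, Myd88, Srebf1 and Col3a1, and windows reaching only 100 bp into the gene ended it for H2-M5, Srebf1 and Gucy1a2.

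The excess of normal-glucose over high-glucose regions, 1831 against 82, was close to that of another pair holding normal-glucose replicate 3, the longest list. Pairing normal-glucose replicate 3 with high-glucose replicate 2 in place of its own replicate gave 1784 regions absent from the remaining 3 libraries. With lists of equal length the counts were 608 for normal and 359 for high glucose, and 3 of the 10 splits gave at least 608, with up to 642. For whole gene ends, equal length turned the balance from 153 normal-glucose and 14 high-glucose genes to 46 and 106, the latter against up to 103 in the other splits. The region count was 13468 without normal-glucose replicate 1, 4064 without normal-glucose replicate 3 and 3038 without high-glucose replicate 2. The gene count was 716 without normal-glucose replicate 1, and 320 and 255 without high-glucose replicates 2 and 3. At a gene end lay 17.3% of the normal-glucose regions (316 of 1831, 95% Wilson interval 15.6 to 19.1) and 16.9% of regions found in a single library.

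**Figure D4:**
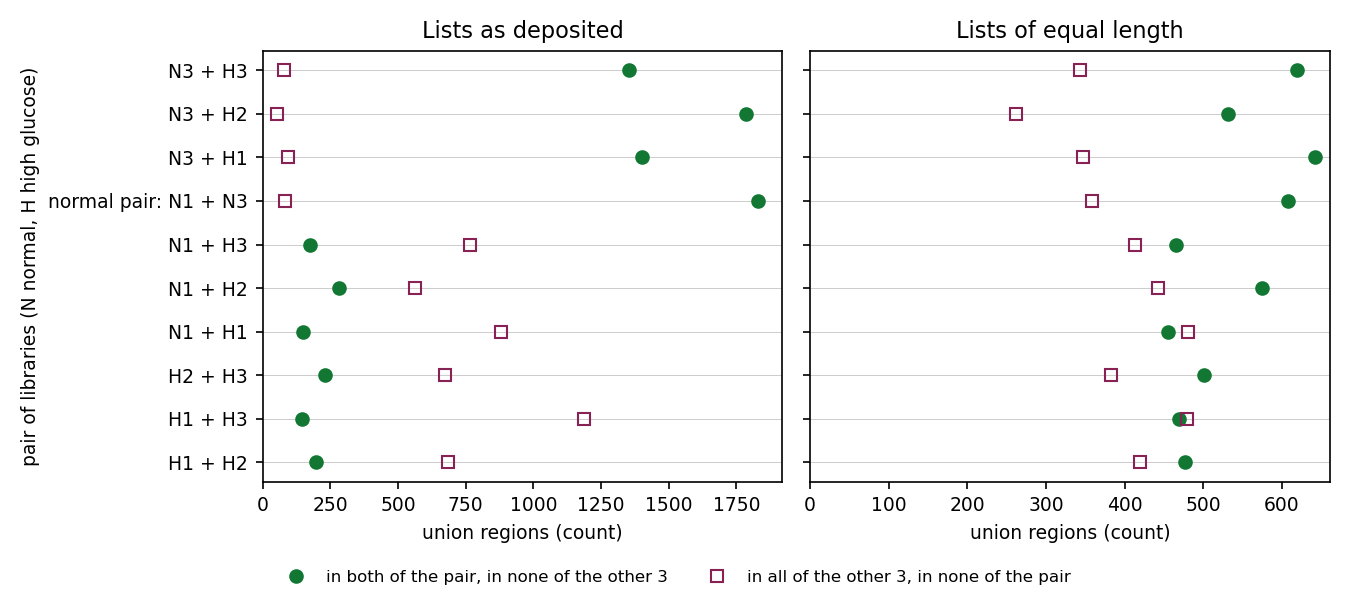
Union regions (count) present in a pair of libraries and absent from the other 3 (filled circles), and the reverse (open squares), for the 10 splits of the 5 libraries. With lists as deposited (left) the 4 pairs that hold normal-glucose replicate 3 give 1352 to 1831 regions and the others 145 to 283, while at equal length (right) all pairs give 455 to 642.

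No gene list passed a test for a difference between the conditions. Of the 23 lists, 0 passed the test of their share of high- against normal-glucose-specific regions (Fisher's exact test over 75 and 1713 assigned regions, smallest adjusted exact p = 1, and 0 lists at an unadjusted p under 0.05). Cushion and valve genes had a gene-end peak at 39.3 ± 2.31 members in high (SD, n = 3) and 44 ± 0 in normal glucose (SD, n = 2). Its p of 0.2 (two-sided exact permutation test) was the smallest possible, shared with endothelial markers, at 1.67 ± 0.577 and 4 ± 1.41, and glucose-responsive genes, at 19.7 ± 0.577 and 21 ± 0. The adjusted value over the 23 lists was 0.986 for each of these. With lists as deposited 19 lists had fewer open members in high glucose and 4 had more, whereas at equal length 8 had fewer and 15 had more. Cushion genes then stood at 39.3 against 39.0, endothelial markers at 1.67 against 2 and glucose-responsive genes at 19.7 against 19.5. At that length p = 0.2 (exact permutation test) fell to mesenchymal markers, at 27.7 against 25, and congenital heart disease genes, at 24.3 against 21.5. Both were higher in high glucose.

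The individually named loci, Nos3, Jarid2, Notch1 and Txnip, held no region specific to a condition. Nos3, the endothelial nitric oxide synthase (chromosome 5, 24364816 to 24384474), had 6 regions within the gene and 10 kb either side, and none was present in all 5 libraries. Each high-glucose library held 1 of them and the normal-glucose libraries 2 and 3 (1 ± 0, n = 3, against 2.5 ± 0.707, n = 2, SD; p = 0.2, exact permutation test). The only region at a Nos3 gene end, 24383524 to 24383702, was in high-glucose replicate 1 alone, at the 0.253 percentile of its list. Jarid2, a partner of the Polycomb repressive complex (chromosome 13, 44730774 to 44921643), had 8 regions, 3 of them in all 5 libraries. One of these, 44730498 to 44730770, lay at the gene end and stood at the 70.7 to 90.5 percentile. Jarid2 regions numbered 4.67 ± 1.53 in high (SD, n = 3) and 7 ± 1.41 in normal glucose (SD, n = 2; p = 0.4, exact permutation test). Notch1, a receptor of the Notch pathway (chromosome 2, 26457902 to 26503822), had 9 regions, none in all 5 libraries, with 4.33 ± 1.53 in high (SD, n = 3) and 6 ± 2.83 in normal glucose (SD, n = 2; p = 0.6, exact permutation test). Normal-glucose replicate 3, the longest list, held 8 regions at Jarid2 and 8 at Notch1, and normal-glucose replicate 1 held 6 and 4. High-glucose replicates 1, 2 and 3 held 5, 6 and 3 at Jarid2, and 3, 6 and 4 at Notch1. These locus counts come from lists as deposited, which differ in length. Txnip (chromosome 3, 96557957 to 96561857) had 1 region, 96557677 to 96557966 over its gene end, present in all 5 libraries at the 81.3 to 95.2 percentile. Whether these regions are exonic, intronic or in untranslated regions was not determined, since the annotation used gave only the ends of each gene.

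**Figure D5:**
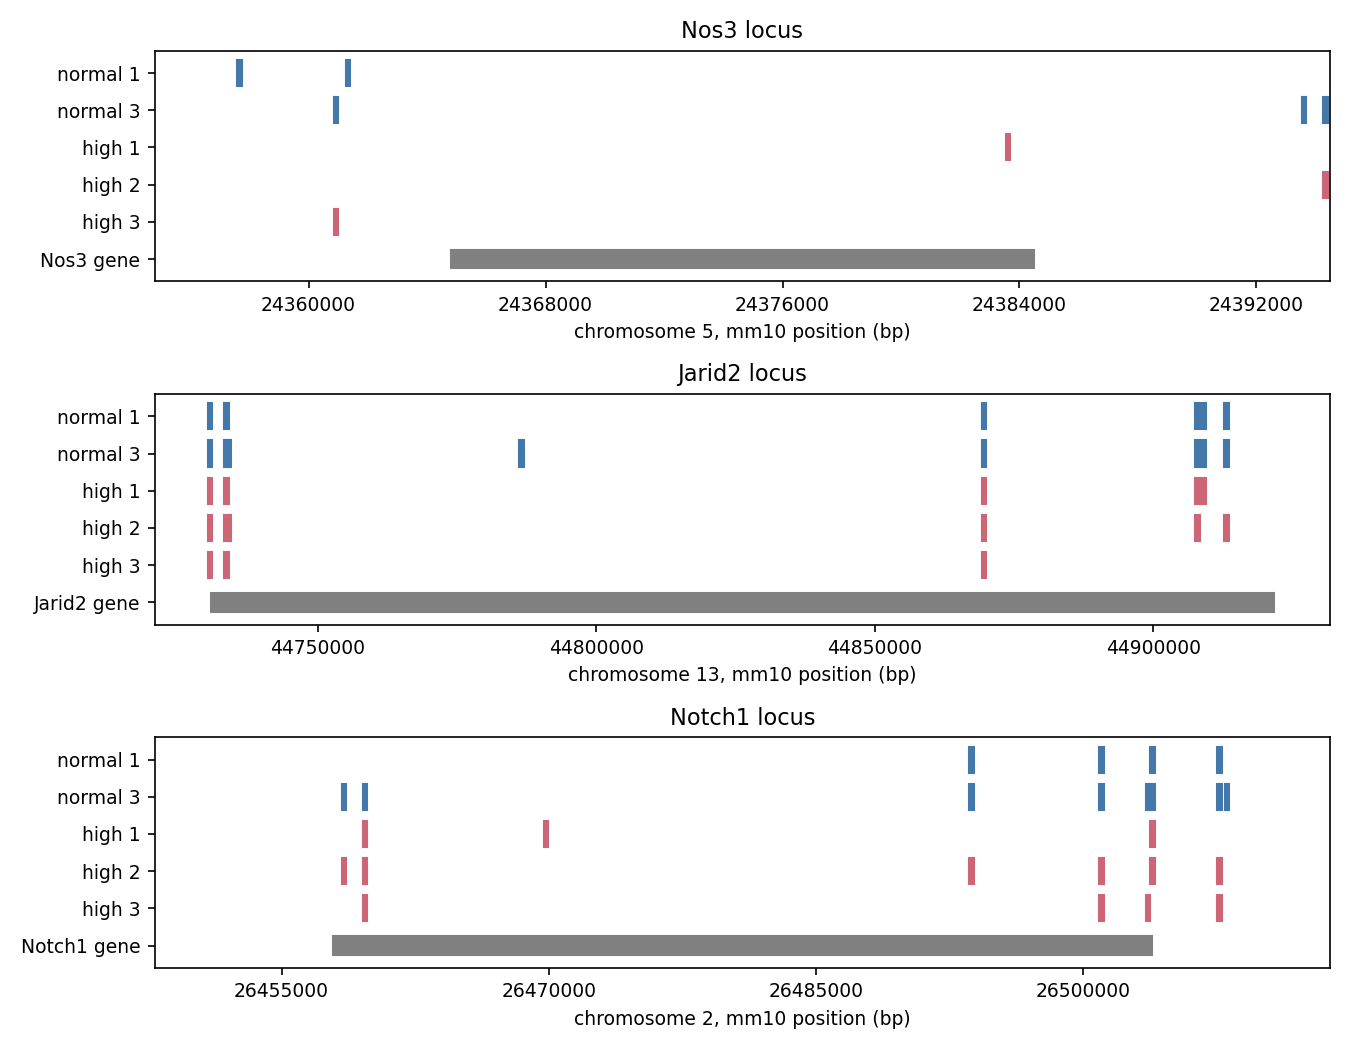
Regions within Nos3, Jarid2 and Notch1 and 10 kb either side, by mm10 position (bp), in each normal-glucose (blue) and high-glucose (red) library. Grey bars are genes, and region marks have a fixed width centred on the region. All 5 libraries share 3 regions at Jarid2 and 0 at Nos3 and Notch1.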

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

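The test of where the peaks of normal-glucose replicate 2 lie was chosen before its result was seen. This library entered no comparison of regions, and 14 of its 66 peaks lay on the mitochondrial genome, against 7 to 9 mitochondrial peaks in each of the other libraries. The remaining 52 nuclear peaks all lay in a region of another library, where randomly moved peaks gave a mean of 0.473 and at most 4 in 1000 draws.

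A candidate explanation for its short list is a low yield of a library with the same open chromatin. All 52 nuclear peaks (100%, 95% Wilson interval 93.1 to 100) lay in regions that all 5 other libraries listed, and 35 lay at a gene end, as that explanation predicts. In the other list where each was weakest, these sites stood at the 59.0 to 100 percentile, most of them near the top. A short list holds mainly such strong sites, so the overlap cannot show that the rest of the open chromatin was the same. What lowered the yield stays open, since reads were not analysed here, and no biological explanation was tested.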

How the results depend on the processing

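Merging within 200 bp was chosen after seeing the data, and the other settings before. With lists of equal length the Jaccard difference reversed to -0.00366. High-glucose-specific regions and genes then numbered 359 and 106, and normal-glucose-specific ones 608 and 46, a setting that removes peaks mainly from normal-glucose replicate 3 by construction. With all 6 libraries the difference in gene-end share reversed to -3.55 points and both normal-glucose counts became 0, by the construction of a library with 66 peaks. A −log10 q of at least 5 gave 51 high-glucose regions, presence in at least 2 libraries gave 655 regions and 66 genes, and a window from 1 kb outside to 100 bp inside a gene end gave 26 genes. The cause of the last change was not tested. Leaving out each library gave 154 to 1184 high-glucose and 2510 to 13468 normal-glucose regions, 26 to 362 and 221 to 716 genes, and peak differences of -9048.5, reversed, to 11093.5. Jaccard differences lay between 0.00305 and 0.0795. The 23 lists gave 0 calls between conditions under each setting run for them. Merging within 200 bp gave 59 and 1726 regions. Openness calls changed with a library left out for mesenchymal markers (adjusted exact p = 0.0397 without normal-glucose replicate 1) and DNA methylation genes (adjusted exact p = 0.0191 without high-glucose replicate 3). The replicate numbers gave little sign of pairing the libraries: deviations of same-numbered libraries correlated at -0.0178, 0.0148 and 0.0274 for replicates 1, 2 and 3. Differently numbered pairs lay between -0.0341 and 0.0192. The value for replicate 2 says little, since normal-glucose replicate 2 held only 52 nuclear peaks. With the replicate block, regions numbered 227 and 3017 and genes 26 and 320, over 2 pairs in place of 5 libraries. Peak and share differences were 1698 (p = 1) and 7.09 points (p = 0.5, exact sign-flip permutation). No block was run for the Jaccard index or the gene lists, and the motif alternatives were not run. Depth in reads is unknown, so a missing peak cannot be told from a site under the threshold.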

Other observations

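Of the tests in this part, the count over splits was chosen only after the result was seen. Some genes, named here after their values were seen, held many regions present in all 5 libraries. Gse1 and Vps13d held 10 such regions each, and Ano6, Sgms1, Smad3, Stard13, Trabd2b and Trio held 7 each. Smad3, a transducer of TGF-beta signalling, was the shortest of those named, with 6.29 shared regions per 100 kb.

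Chromosome X had 18.7 shared regions per 100 genes, against a median of 60.5 over the 19 autosomes. Among the autosomes, gene-end peaks open in all 5 libraries had the lowest median percentile on chromosome 14 in every library, from 71.9 to 85.6.

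Normal-glucose-specific regions outnumbered high-glucose-specific ones, 1831 to 82. The requirement of 3 rather than 2 high-glucose libraries is argued against as the whole cause, since 2 against 2 libraries still gave a ratio of at least 7.89. Unequal list length remained a candidate cause, as its prediction was met: at equal length the count was 608, under the 642 of another split. Simulated lists with planted regions in equal number and no other difference called 2521 against 93 beyond them with full lengths and 723 against 419 at equal length. The simulation drew its regions from these same lists with a noise level not fitted to them, so the size of its counts cannot be set against the observed ones. An effect of glucose stays open, because the equal-length Jaccard difference of -0.00366 met the bound of 0 set against it beforehand but by less than the SD of the other splits, 0.00748, a margin added after the value was seen. With 10 splits no share under 0.05 is possible, and 1 split, the real one, gave 1831 regions, with 1784 as the highest other.

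Chromosome 15 had the most shared regions per 100 genes, 84.3, against 71.8 for the next autosome. Extra copies of chromosome 15 may be a candidate explanation, as they would raise peak strength along it. By the median percentile of gene-end peaks open in all 5 libraries, chromosome 15 had rank 1 of 19 over the library means, at 85.5 against a median of 82.2 (SD over autosomes 2.31). It had rank 1 in 2 libraries and ranks 2, 3 and 4 in the others, and chromosome 19 was close, at 85.2. The prediction fixed beforehand for extra copies, rank 1 in every library, was therefore not met. The opposing one, a mean at or below the median of the autosomes, was not met either. Copy number and the density of strong genes cannot be told apart here, since peak lists hold no read depth.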
